A study of Homo sapiens with 16 samples.

How the data were processed

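Single-end reads of 101 bases from poly-A selected libraries (Illumina TruSeq, sequenced on an Illumina HiSeq) underlie the data, per the labels' protocols. Per the submitters' processing notes, the tools named are bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3 and HTSeq, and the genome build is GRCh37. The annotation release, the treatment of reads that map to several places and the use of strand are not given in the sources used here. The deposited values are whole-number read counts per gene, 1 column per library over 25559 gene entries. Gene families with near-identical copies, such as HSPA1A with HSPA1B or PRSS1 with its relatives, and overlapping or antisense genes therefore carry uncertain counts. Gene symbols are those of the files, some of them older names (PKM2, IGJ). By symbol or synonym, 22503 names (88.04%) were found in a reference gene table of another build, so no coordinates are given. Entries of Y-linked genes and XIST (135) were left out of every step, and 25424 were used. The files hold 0 mitochondrially encoded genes.

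Groups were taken from the labels: pancreas (5 libraries), jejunum (5), PLN (3) and blood (3). Replicate numbers stand for the organ donor, so PLN has replicates 2, 3 and 5, and blood numbers name other people. The series states that the tissues are donor-matched. As a check, the deviations of same-numbered libraries from their group means were correlated; all 11 pairs lay over 0.1, between 0.118 and 0.629. The mark of 0.1 alone does not part donors, as correlations between libraries of different numbers reached 0.146. The margin was smallest for replicate 2 of pancreas and jejunum, at 0.118 against 0.0987 with another number. Within groups 0 pairs of libraries were identical, and the lowest chi-square per gene between any 2 replicates was 44.8.

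Counts were normalized by TMM, filtered with filterByExpr and tested with edgeR's quasi-likelihood test (robust, two-sided) with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 3 comparisons among tissues used the 13 organ donor libraries with the donor as a block (14534 genes). The 3 comparisons with blood used all 16 libraries without a block (14992 genes), since blood came from other people. Log2 fold changes are first minus second group, given with the standard error; levels are counts per 1e6 counts (CPM) as mean ± SD. The median log2 fold change of all genes lay between −0.01 and 0.07 under TMM and reached 0.10 under RLE for pancreas against blood. Genes called alike in several comparisons were counted, and set beside the count in 20 simulations of unchanged groups. These simulations hold no true difference, so they do not give the overlap of groups that do differ.

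A total of 31 gene lists, 11 of them markers of cell types, were tested in the 6 comparisons (186 tests) with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all tests. Of these tests 81 passed, and 0 passed with a correlation estimated per list; fry was run beside them. Of the listed genes 647 were found and 9 were not. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each comparison, the 8 genes of smallest p in each direction with an absolute log2 fold change above 1, a mean above 10 CPM in the higher group and the same direction in every donor pair, or no overlap between groups for blood. It also took up to 4 members of each list, called ones first, by absolute log2 fold change, and always PDCD1, ITGAE, ITGA1, CXCR6, CD101, CCR9, CX3CR1, S1PR1, KLF2, IFNG and GZMB. Results for some genes the rule took are not reported here. Y-linked genes, XIST, variable, diversity and joining segments of immunoglobulins and T cell receptors, KIR, HLA-DRB and HLA-DQ genes, GSTM1, GSTT1, UGT2B17, mitochondrial and ribosomal RNA genes and genes without a symbol were not eligible for the first part. The text prints a part of the genes the rule took, with preference for those called under every alternative.

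Floors for a group at 0 are 3 counts over the group and cover counting error only, as PCR copies are not independent molecules. The tests were run on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per comparison. At 4-fold they recovered 64% for pancreas against jejunum, 52% for pancreas against PLN, 49% for jejunum against PLN, 40% for pancreas against blood, 55% for jejunum against blood and 32% for PLN against blood. At 2-fold the same comparisons gave 22%, 13%, 7%, 7%, 9% and 1%, with 0 to 4 unchanged genes called and 0 wrong signs. Far fewer genes changed than were called in the data, which makes the adjustment stricter, and no donor effect was drawn. These shares are therefore not the recovery in the data. A simulated moved list in pancreas against blood had a camera adjusted p of 9.55e-17, or 1.9e-05 with an estimated correlation, and 0 of the other lists were called. The simulated genes were drawn independently of each other. This run therefore cannot tell how often lists of correlated genes pass wrongly at the preset correlation. Alternatives were RLE normalization, DESeq2, no low-count filter, no robust estimation, a model of the 2 groups alone, no donor block (or donor as a random block in limma voom for blood), a 2-fold threshold and leaving out each library. Donors 1 and 4 gave a pancreas and a jejunum library only. With the donor block, leaving out either library takes that donor's pair out of pancreas against jejunum, so these fits are not separate alternatives. Fits without the 2 pancreas libraries richest in acinar RNA (replicates 1 and 2), without the 2 jejunum libraries with most acinar or heat shock RNA (replicates 3 and 4), and with the log2 acinar marker level as a covariate were added after seeing the data. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.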

Results

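The series profiled messenger RNA of sorted human CD8 T cells in 16 libraries: 5 from the pancreas, 5 from the jejunum, 3 from the lymph nodes that drain the pancreas (PLN) and 3 from blood. The tissue cells were memory cells (CD45RA and CCR7 negative) that carried CD69, a surface protein used to mark tissue-resident memory T cells, which stay in a tissue and do not recirculate. They came from 5 organ donors, each of whom gave a pancreas and a jejunum sample, and 3 of whom also gave PLN. The blood cells were effector memory cells (TEM) without CD69 from 3 other, healthy donors. The comparisons ask how resident cells of the pancreas differ from those of other sites in the same people and from circulating memory cells. The gene for the inhibitory receptor PD-1 (PDCD1) was of stated interest. Library totals (in 1e6 counts) ran from 16.9 to 24.6. Their means were 18.1 ± 0.963 (SD) in pancreas, 22.0 ± 2.79 in jejunum, 20.8 ± 0.986 in PLN and 19.3 ± 0.384 in blood. Between 15161 and 17543 genes were detected per library.

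Blood and pancreas were set apart from the other sites on the first 2 principal components of the 1000 most variable genes. PC1 held 40.6% of the variance and set blood (−73.7 to −65.0) apart from all tissue libraries (−17.8 to 42.1). PC2 held 27.6%, with the pancreas libraries (13.9 to 51.7) above those of jejunum (−41.4 to −5.61) and PLN (−41.6 to −15.0). Within pancreas, PC2 ran in the order of the summed acinar markers described below, from replicate 2 (51.7, 37014 CPM) to replicate 5 (13.9, 983 CPM). Jejunum replicate 3, with most acinar RNA of its group (4972 CPM), lay highest in jejunum (−5.61). It still lay below pancreas replicates 3 and 5, which held less (2061 and 983 CPM). PC2 thus cannot be read as site alone.

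**Figure D1:**
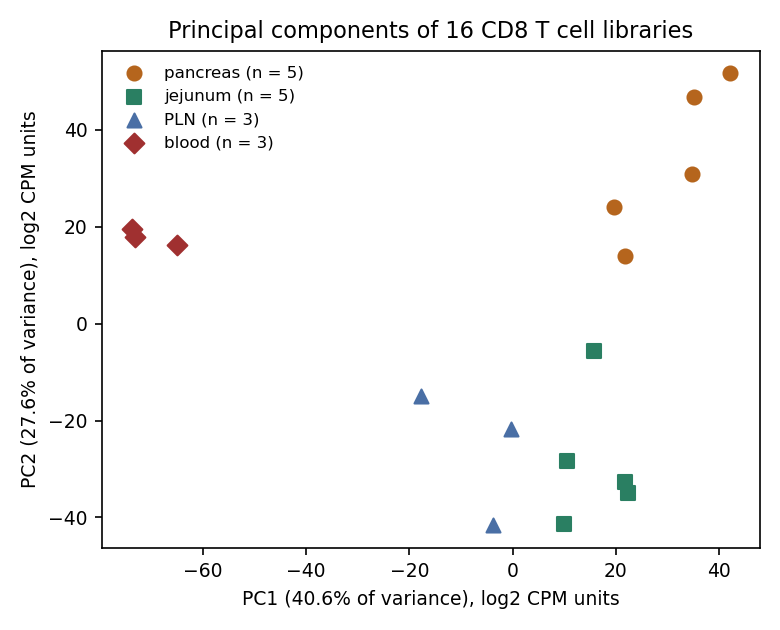
Each point is a library on the first 2 principal components of log2 CPM over 1000 genes, with PC1 (40.6% of variance) on the x axis and PC2 (27.6%) on the y axis. The 3 blood libraries lie at or below −65.0 on PC1, and the 5 pancreas libraries lie above the jejunum and PLN libraries on PC2.

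Transcripts of cells other than CD8 T cells were present in amounts that differed between sites. The 31 acinar markers, which encode digestive enzymes and secreted proteins of the exocrine pancreas (4 of them also known from intestine), summed to 15898 ± 16432 CPM (SD, n = 5) in pancreas, with a range of 983 to 37014. The sort on CD3 and CD8 selects against acinar cells, but its purity was not tested here, so carried-over cells are not excluded. These markers summed to 1084 CPM on average in jejunum (53.2 to 4972, n = 5; 112 without replicate 3), 478 in PLN (45.2 to 825, n = 3; 305 without replicate 3) and 23.3 in blood (22.2 to 24.8, n = 3). PRSS1, CPA1 and REG1A had 0 counts in all 3 blood libraries, so the pancreas means were at least 61900-fold, 27300-fold and 53500-fold higher against a floor of 3 counts over the group (16900-fold for CPA1 without pancreas replicate 1 and 28600-fold for REG1A without pancreas replicate 2). Against the same floor the jejunum means of PRSS1, CPA1 and REG1A were at least 3070-fold, 1180-fold and 3300-fold higher, but 291-fold, 123-fold and 370.0-fold without jejunum replicate 3. The PLN means were at least 1430-fold (847-fold without PLN replicate 3), 600.0-fold and 1290-fold higher. Duct and epithelial markers averaged 695 CPM in pancreas (80.0 to 2210, and 316 without replicate 2), 42.3 in jejunum, 40.6 in PLN and 5.63 in blood. Transcripts of red cells and platelets averaged 412 CPM in blood (146 to 626) against 25.4 in pancreas, 58.0 in jejunum (26.7 without replicate 4) and 31.6 in PLN (9.72 without replicate 2). Those of macrophages and dendritic cells ranged from 61.4 to 759 CPM in blood (mean 429, and 264 without replicate 1). Their means were 70.5 in pancreas, 72.6 in jejunum (34.7 without replicate 4) and 92.3 in PLN (31.6 without replicate 5), so blood replicate 3 lay below all 3 means.

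**Figure D2:**
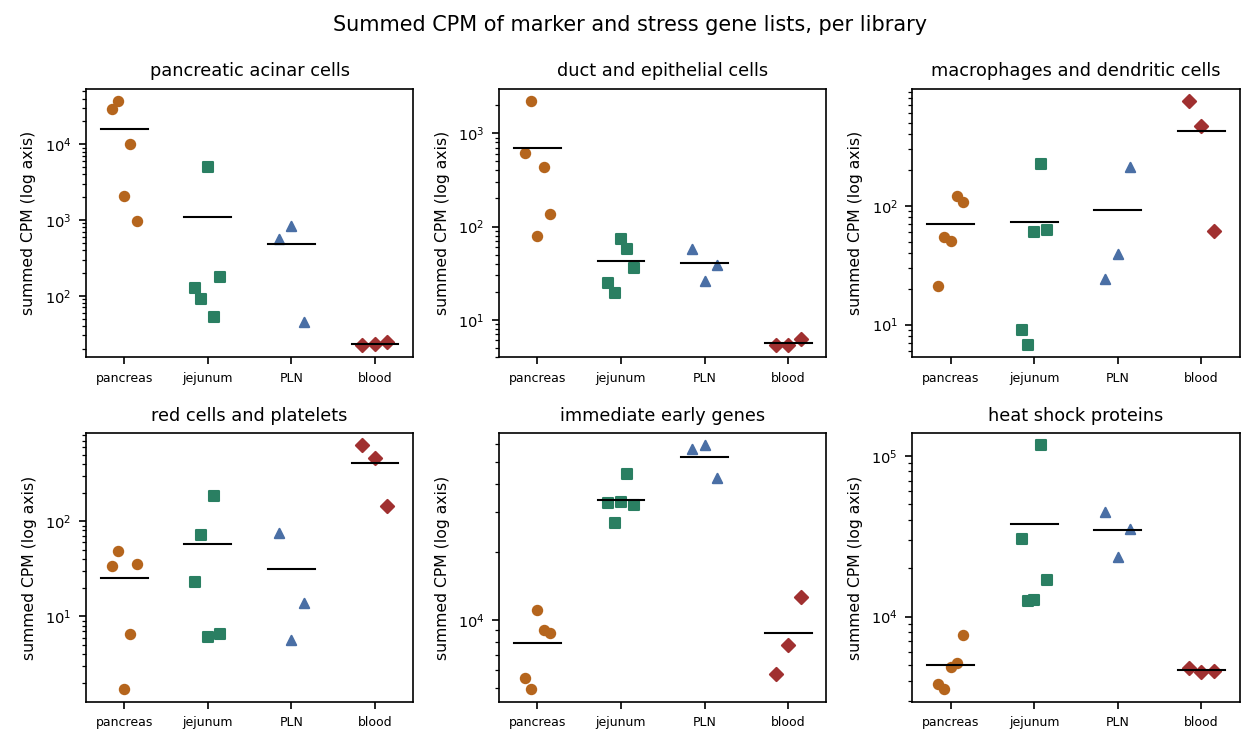
Summed CPM (y axis, log scale) of 6 gene lists in each library, grouped by site on the x axis; points are libraries and bars are means. Acinar markers range from 983 to 37014 CPM in pancreas, and immediate early genes average 7894 CPM in pancreas, 34016 in jejunum, 53043 in PLN and 8731 in blood.

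**Figure D3:**
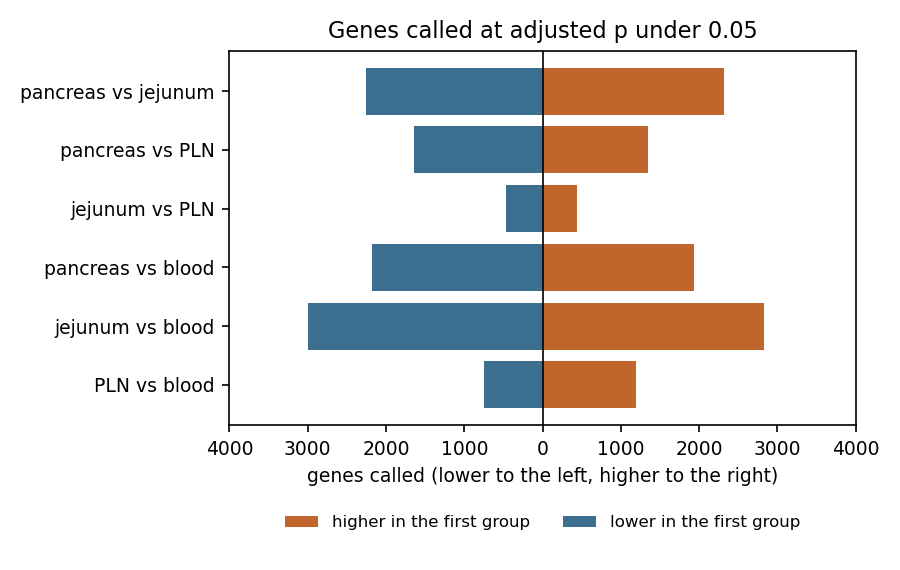
Number of genes called at an adjusted p under 0.05 (x axis) in each of the 6 comparisons (y axis), with genes lower in the first-named group to the left of 0 and genes higher in it to the right. The counts range from 902 for jejunum against PLN to 5832 for jejunum against blood.

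Compared with the jejunum of the same donors, CD8 T cells of the pancreas held less RNA of activation-induced genes, chaperones and several surface receptors. They held more RNA of some oxidative phosphorylation genes. FOS, a subunit of the AP-1 transcription factor, was at 109 ± 48.5 CPM (SD, n = 5) in pancreas and 3872 ± 1118 in jejunum (log2 fold change −5.20 ± 0.30 SE, adjusted p = 5.43e-06). KLF2, a transcription factor that drives expression of receptors for leaving tissue, was at 6.32 ± 2.14 and 207 ± 119 CPM (log2 fold change −4.68 ± 0.51, adjusted p = 0.000242). CCR9, the chemokine receptor that guides T cells to the small intestine, was at 1.57 ± 0.980 and 334 ± 291 CPM (log2 fold change −7.55 ± 1.09, adjusted p = 0.00200). Of 14534 genes tested, 4572 differed, 2311 higher and 2261 lower in pancreas, and each gene named below as rising or falling did so in all 5 donor pairs.

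Of 31 immediate early genes, which are transcribed within minutes of a stimulus, 26 fell and 5 did not pass (27 fell when adjusted over the list alone; camera adjusted p = 1.15e-13, adjusted p = 0.131 with an estimated correlation). They included NR4A3 (−3.79 ± 0.40), FOSB (−3.72 ± 0.53) and ATF3 (−3.29 ± 0.49). Of 17 heat shock proteins, 9 fell (12 adjusted over the list alone; camera adjusted p = 4.88e-07, adjusted p = 0.527 with an estimated correlation). The chaperone genes HSPA8 (−3.39 ± 0.46), HSPH1 (−3.16 ± 0.75) and HSP90AA1 (−2.76 ± 0.45) were among them. Jejunum replicate 4 had the highest summed heat shock level, 115920.1 CPM, where the other 4 jejunum libraries lay between 12441 and 30479. Of 23 NF-kB targets, 8 fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 0.00272, adjusted p = 0.592 with an estimated correlation). Among them were REL (−1.53 ± 0.34), a subunit of NF-kB, and the survival gene BCL2A1 (−1.81 ± 0.33). These 3 lists were read in libraries whose acinar transcripts also differed, and with the acinar level as a covariate 4 immediate early genes were called lower (median log2 fold change −1.42, against −1.82).

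Genes of residency and receptor function also moved. Of 20 genes listed as higher in resident cells, 8 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.592 with an estimated correlation). The falling members included RGS1 (−3.42 ± 0.50), a brake on chemokine receptor signalling, CRTAM (−2.49 ± 0.42), an adhesion receptor, and CD101 (−1.87 ± 0.35), an inhibitory surface protein. The integrin genes ITGAE and ITGA1, which encode CD103 and CD49a, did not pass the test, at 0.43 ± 0.34 (adjusted p = 0.352) and 0.23 ± 0.41 (0.702). The chemokine receptor gene CXCR6 stood at 1.12 ± 0.65 (0.222), the cytokine gene IFNG at −0.79 ± 0.65 (0.382) and the granzyme gene GZMB at 0.55 ± 0.64 (0.545). Of 19 inhibitory receptors and ligands, 6 fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 0.00955, adjusted p = 0.497 with an estimated correlation). These included CD160 (−4.73 ± 0.45) and LAYN (−2.90 ± 0.54). PDCD1 averaged 249.8 ± 209 CPM in pancreas and 97.5 ± 89.7 in jejunum, higher in pancreas in 4 of 5 donor pairs (log2 fold change 1.37 ± 0.56, adjusted p = 0.0893); without jejunum replicate 3 its adjusted p was 0.0464 at 1.83, DESeq2 gave 0.0107 at 1.33, and all alternatives gave 0.0107 to 0.239. S1PR1 (−0.82 ± 0.54, adjusted p = 0.273), the receptor for exit from tissue, passed only without jejunum replicate 1 (−1.36, 0.0199) or pancreas replicate 1 (−1.36, 0.0197), and all alternatives gave 0.0197 to 0.562. With the donor block both of these fits leave out the pair of donor 1, so they are not separate alternatives. CX3CR1 (−0.36 ± 1.21, 0.846) did not pass.

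Of 23 circulation and egress genes, 7 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.00132, adjusted p = 0.456 with an estimated correlation). RASGRP2, an activator of integrin signalling, stood at −2.87 ± 0.21, and 4 of the list fell without pancreas or jejunum replicate 4. Of 20 NK receptors and innate-like genes, 6 fell (6 adjusted over the list alone; camera adjusted p = 0.000649, adjusted p = 0.456 with an estimated correlation), including KLRD1 (−1.61 ± 0.34), which encodes CD94. Of 17 naive and central memory genes, 10 fell and 3 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.0456, adjusted p = 0.369 with an estimated correlation), with LRRN3 at −5.62 ± 0.94 and NELL2 at 3.39 ± 0.51. Mast cell markers fell beside them (3 of 6, 6 adjusted over the list alone; camera adjusted p = 0.00157, adjusted p = 0.520 with an estimated correlation; 5 without jejunum replicate 2). Stromal and endothelial markers fell too (5 of 20, 4 adjusted over the list alone; camera adjusted p = 0.000649, adjusted p = 0.592 with an estimated correlation). That count was 3 without pancreas replicate 2 or 5 or jejunum replicate 3, 2 without pancreas replicate 4 and 1 without jejunum replicate 4 or 5. Of the B and plasma cell markers 5 fell and 1 rose. They summed to 13.2 to 42.6 CPM in pancreas and 91.7 to 934 in jejunum.

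Among genes higher in pancreas, 8 of 32 oxidative phosphorylation genes rose and 0 fell (the same count adjusted over the list alone; camera adjusted p = 0.00955, adjusted p = 0.776 with an estimated correlation). They included COX4I1 (1.29 ± 0.23) and NDUFB10 (1.42 ± 0.25), subunits of the respiratory chain. For scale, 2311 of all 14534 genes tested rose and 2261 fell. Of 29 genes of T cell receptor signalling, 8 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.560, adjusted p = 0.863 with an estimated correlation), with 3 falling without pancreas replicate 2. The adaptor SIT1 stood at 2.12 ± 0.29 and the phosphatase gene UBASH3B at −2.71 ± 0.56. GPR25, an orphan receptor gene, rose by 4.89 ± 0.81, IL16, a cytokine gene, by 2.11 ± 0.29 and PKM2, listed under its older symbol for the glycolytic enzyme pyruvate kinase, by 1.65 ± 0.23. Of 15 duct and epithelial markers, 7 rose, among them CFTR (5.38 ± 0.80; 4.37 without jejunum replicate 2) and ELF3 (4.38 ± 0.66), with 10 adjusted over the list alone (camera adjusted p = 5.01e-06, adjusted p = 0.520 with an estimated correlation). The count was 3 without pancreas or jejunum replicate 1 and 4 without pancreas or jejunum replicate 4. Of 31 acinar markers, 6 rose, 24 adjusted over the list alone (camera adjusted p = 2.88e-09, adjusted p = 0.592 with an estimated correlation). Leaving out 1 library gave between 0 (without pancreas or jejunum replicate 2 or 4) and 27 (without pancreas replicate 3). It gave 1 without pancreas or jejunum replicate 1, 2 without jejunum replicate 5 and 25 without jejunum replicate 3. The number of genes called was 2619 without the 2 pancreas libraries richest in acinar RNA, 2522 without the 2 jejunum libraries with most acinar or heat shock RNA, and 217 with the acinar level as a covariate.

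Against the PLN of the same donors, pancreas cells held less RNA of activation-induced genes, of receptors and transcription factors of recirculating T cells, and of genes typical of mucosal-associated invariant T (MAIT) cells. They held more RNA of the integrin CD103, a call that was lost without PLN replicate 2. Of 14534 genes, 2983 differed, 1345 higher and 1638 lower in pancreas (5 pancreas and 3 PLN libraries, with 3 donor pairs). KLF2 stood at 6.32 ± 2.14 CPM in pancreas and 525 ± 229 in PLN (SD; log2 fold change −5.90 ± 0.60 SE, adjusted p = 0.000231). FOS stood at 109 ± 48.5 and 4506 ± 1539.5 CPM (log2 fold change −5.11 ± 0.32, adjusted p = 1.11e-05). Each gene named below as rising or falling moved alike in all 3 donor pairs.

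Of 31 immediate early genes, 27 fell (28 adjusted over the list alone; camera adjusted p = 1.9e-20, adjusted p = 0.105 with an estimated correlation). Besides FOS they included the orphan nuclear receptor genes NR4A1 (−5.76 ± 0.77) and NR4A3 (−5.26 ± 0.46). Of 23 circulation and egress genes, 13 fell and 2 rose (14 and 3 adjusted over the list alone; camera adjusted p = 5.07e-09, adjusted p = 0.155 with an estimated correlation). KLRG1, a receptor of differentiated effector cells, stood at −4.74 ± 0.85 and RASGRP2, an activator of integrin signalling, at −3.89 ± 0.25. The number falling was 8 without PLN replicate 5. S1PR1 stood at −3.05 ± 0.67 (adjusted p = 0.0117; 0.0504 at −2.99 without PLN replicate 5; all alternatives gave 1.81e-06 to 0.0504). CX3CR1 did not pass (−0.66 ± 1.31, adjusted p = 0.752), and its log2 fold change turned to 0.383 without pancreas replicate 3. Of 17 naive and central memory genes, 9 fell (10 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.23e-05, adjusted p = 0.131 with an estimated correlation). The transcription factor LEF1 stood at −5.83 ± 0.57 and CCR7, whose protein was a sort criterion, at −4.23 ± 0.71. Of 15 MAIT and type 17 genes, 8 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 3.99e-05, adjusted p = 0.155 with an estimated correlation). These included SLC4A10 (−5.44 ± 0.51) and IL23R (−5.43 ± 0.98), the receptor for interleukin 23. CXCR5, the receptor that guides cells to B cell follicles, fell by 7.02. These genes fell beside B and plasma cell markers, of which 11 of 14 fell (12 adjusted over the list alone; camera adjusted p = 6.13e-07, adjusted p = 0.397 with an estimated correlation). The count was 6 without PLN replicate 2, 3 or 5 or pancreas replicate 3, and 7 without pancreas replicate 5.

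In the same comparison, 12 of 17 heat shock proteins fell (13 adjusted over the list alone; camera adjusted p = 3.43e-08, adjusted p = 0.520 with an estimated correlation). DNAJA1 stood at −3.96 ± 0.45, and 6 of the list fell without PLN replicate 2 and 7 without PLN replicate 5. Of 20 residency genes, 8 fell and 2 rose (the same counts adjusted over the list alone; camera adjusted p = 0.0541, adjusted p = 0.623 with an estimated correlation). The number rising was 0 without PLN replicate 2 and 1 without PLN replicate 3 or pancreas replicate 2 or 3. Among these genes ITGAE rose to 589 ± 341 CPM against 156 ± 121 (log2 fold change 2.15 ± 0.46, adjusted p = 0.00780; 0.0596 at 1.92 without PLN replicate 2; all alternatives gave 5.28e-06 to 0.0596). ITGA1 stood at 1.85 ± 0.54 (adjusted p = 0.0338) and lost its call without PLN replicate 2 (0.124 at 1.86), PLN replicate 3 (0.117 at 1.23), pancreas replicate 2 (0.0824 at 1.69) or pancreas replicate 3 (0.0536 at 1.49), and without the low-count filter (0.0677 at 1.78); all alternatives gave 0.000903 to 0.124. CCR9 (−3.42 ± 1.14, adjusted p = 0.0691) passed without PLN replicate 2 (0.044 at −4.44), pancreas replicate 2 (0.0135 at −4.29) or the donor block (0.0134 at −4.53), and with DESeq2 (0.00745 at −3.37). It stood at −1.69 (0.227) without PLN replicate 5, the library with most of its PLN counts; all alternatives gave 0.00745 to 0.227. CXCR6 (1.82 ± 0.80, adjusted p = 0.136) passed only without the donor block (0.0402 at 2.41; all alternatives gave 0.0402 to 0.367) and GZMB (2.15 ± 0.79, 0.0816) only without pancreas replicate 3 (0.0404 at 2.65; all alternatives gave 0.0404 to 0.300). GZMB stood at 0.989 (0.172) without pancreas replicate 5, and CXCR6 at 2.88 (0.0559) without PLN replicate 2. PDCD1 (1.15 ± 0.66, 0.246), CD101 (−0.99 ± 0.41, 0.103) and IFNG (−0.90 ± 0.67, 0.369) did not pass. Of 19 inhibitory receptors and ligands, 6 fell (6 adjusted over the list alone; camera adjusted p = 0.00138, adjusted p = 0.369 with an estimated correlation), 3 without PLN replicate 3 or 5. CD160 stood at −4.90 ± 0.51. GZMA, a granzyme gene, fell by 2.60 and FASLG, the death ligand gene, rose by 2.09. Of 27 glycolysis and hypoxia genes, 9 rose and 0 fell (the same count adjusted over the list alone; camera adjusted p = 0.0187, adjusted p = 0.742 with an estimated correlation). GAPDH stood at 2.20 ± 0.38 and PGAM1 at 1.77 ± 0.29. The count was 3 without PLN replicate 3 or 5, 4 without PLN replicate 2 or pancreas replicate 5 and 5 without pancreas replicate 3. Duct and epithelial markers were higher beside them (10 of 15 rose, 11 adjusted over the list alone; camera adjusted p = 2.77e-05, adjusted p = 0.520 with an estimated correlation). The count fell to between 2 and 6 without PLN replicate 2 (2), 3 (3) or 5 (3) or pancreas replicate 1 (6), 2 (3), 4 (5) or 5 (4). Of 31 acinar markers 1 rose, 27 adjusted over the list alone (camera adjusted p = 2.74e-08, adjusted p = 0.592 with an estimated correlation). The count was 25 without pancreas replicate 3 and 0 without pancreas replicate 2, 4 or 5 or PLN replicate 2, 3 or 5. Of 10 CD4 and regulatory T cell markers 4 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0282, adjusted p = 0.527 with an estimated correlation), with 2 falling without PLN replicate 2 or 5. The number of genes called was 1441, 1673 and 1284 without PLN replicates 2, 3 and 5, 1720 with only these 2 groups in the model and 409 with the acinar level as a covariate.

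Jejunum and PLN differed at fewer genes in the fit of all organ donor libraries. With only the 2 groups in each model the count was 1624, close to the 1720 of pancreas against PLN. Of 14534 genes, 902 differed, 436 higher and 466 lower in jejunum (5 jejunum and 3 PLN libraries), and each gene named as rising or falling moved alike in all 3 donor pairs. The MAIT-associated transporter gene SLC4A10 stood at 2.08 ± 1.04 CPM in jejunum and 63.0 ± 31.9 in PLN (SD; log2 fold change −4.59 ± 0.50 SE, adjusted p = 0.00258), and NCR3, which encodes the activating receptor NKp30, at 1.79 ± 2.06 and 42.1 ± 34.7 CPM (log2 fold change −4.36 ± 0.48, adjusted p = 0.00258). The receptor tyrosine kinase gene LTK (−3.32 ± 0.40) and the activation marker CD83 (−3.14 ± 0.38) also fell. DAAM1 (2.66 ± 0.28), a regulator of actin assembly, WEE1 (2.46 ± 0.28), a kinase that restrains entry into mitosis, FAM102B (2.36 ± 0.29) and ZSCAN22 (2.44 ± 0.29) rose. Of 15 MAIT and type 17 genes, 5 fell (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.3e-05, adjusted p = 0.133 with an estimated correlation). Only 3 fell without PLN replicate 2 or 3 or jejunum replicate 2 or 3. Of 31 immediate early genes, 8 fell (15 adjusted over the list alone; camera adjusted p = 7.43e-05, adjusted p = 0.369 with an estimated correlation). However, 0 fell without PLN replicate 2 or 3 or jejunum replicate 2, 1 without jejunum replicate 3, 2 without jejunum replicate 5 and 5 without PLN replicate 5. Of 23 circulation and egress genes, 6 fell (11 adjusted over the list alone; camera adjusted p = 1.28e-06, adjusted p = 0.256 with an estimated correlation). The count was 0 without PLN replicate 2 or 3 and 1 without PLN replicate 5 or jejunum replicate 2 or 5. B and plasma cell markers fell with them (6 of 14, 9 adjusted over the list alone; camera adjusted p = 0.000409, adjusted p = 0.520 with an estimated correlation). That count was 1 without PLN replicate 2 or 3, and 2 without PLN replicate 5 or jejunum replicate 2, 3 or 5. Stromal and endothelial markers rose (3 of 20, 6 adjusted over the list alone; camera adjusted p = 0.00129, adjusted p = 0.592 with an estimated correlation), but 0 without PLN replicate 2 or 3 or jejunum replicate 2 or 5 and 1 without PLN replicate 5 or jejunum replicate 3. Of 6 mast cell markers 2 were higher adjusted over the list alone (camera adjusted p = 0.00245, adjusted p = 0.520 with an estimated correlation).

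Of the 134 genes named for this comparison 60 were called, and 8 of those kept the call under every alternative. CCR9, at 334 ± 291 CPM in jejunum and 37.7 ± 58.6 in PLN, had a log2 fold change of 4.14 ± 1.25 (adjusted p = 0.0887; 0.0425 at 5.75 without PLN replicate 5, 0.0761 at 5.14 without jejunum replicate 5, and 0.000978 at 4.28 with DESeq2; all alternatives gave 0.000978 to 0.340). ITGA1 (1.62 ± 0.53, 0.0869) passed with DESeq2 only (0.00645 at 1.64; all alternatives gave 0.00645 to 0.299). KLF2, CD101, CXCR6, GZMB, IFNG, PDCD1 and CX3CR1 did not pass, with log2 fold changes of −1.22 ± 0.50, 0.88 ± 0.40, 0.70 ± 0.86, 1.60 ± 0.74, −0.10 ± 0.78, −0.22 ± 0.67 and −0.30 ± 1.12. CXCR6 stood at 1.72 without PLN replicate 2. ITGAE (1.72 ± 0.44, adjusted p = 0.0419) and S1PR1 (−2.23 ± 0.58, 0.0494) passed with all libraries, and each lost its call without PLN replicate 2 (0.175 and 0.0985), PLN replicate 3 (0.215 and 0.249), jejunum replicate 2 (0.107 and 0.0997), jejunum replicate 3 (0.0954 and 0.0984), jejunum replicate 4 (0.0576 and 0.0667) or jejunum replicate 5 (0.0914 and 0.0931). S1PR1 also lost it without PLN replicate 5 (0.142), with RLE (0.0509) and without the low-count filter (0.0935). Without the donor block both lost it (0.157 and 0.107). Where the call was lost the log2 fold changes lay between 1.26 and 1.84 for ITGAE and between −2.60 and −1.85 for S1PR1. ITGAE stood at 2.47 without PLN replicate 5. For ITGAE and S1PR1 all alternatives gave 0.000772 to 0.215 and 0.00182 to 0.249. The number of genes called was 21, 19 and 229 without PLN replicates 2, 3 and 5, and 53, 161 and 219 without jejunum replicates 2, 3 and 5. It was 330 without the 2 jejunum libraries with most acinar or heat shock RNA, 234 without the donor block, 1624 with only these 2 groups in the model and 2159 with DESeq2.

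Against blood, pancreas cells lacked most RNA of receptors for circulation and of proliferation, and carried high levels of residency integrins and of genes induced by TGF-beta. Of 14992 genes, 4101 differed, 1928 higher and 2173 lower in pancreas (5 against 3 libraries). ITGAE stood at 589 ± 341 CPM in pancreas and 36.1 ± 3.44 in blood (SD; log2 fold change 4.03 ± 0.65 SE, adjusted p = 0.000390), and ITGA1 at 355 ± 279.7 and 11.9 ± 13.4 (log2 fold change 4.90 ± 0.86, adjusted p = 0.000781; 6.396 without blood replicate 3). CX3CR1, the fractalkine receptor of circulating effector cells, stood at 0.353 ± 0.254 and 524 ± 116 CPM (log2 fold change −10.49 ± 1.96, adjusted p = 0.00183). The groups also differed in donors, in the CD69 gate and in passage through tissue digestion, so site cannot be separated from these. The pancreas libraries of each gene named below as rising or falling did not overlap with those of blood.

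Of 23 circulation and egress genes, 21 fell (22 adjusted over the list alone; camera adjusted p = 2.56e-16, adjusted p = 0.155 with an estimated correlation). Among them were S1PR1 (−6.62 ± 0.89) and KLF2 (−5.46 ± 0.58). Of 27 cell cycle genes, 25 fell (the same count adjusted over the list alone; camera adjusted p = 4.08e-15, adjusted p = 0.256 with an estimated correlation). Examples were MKI67 (−6.96 ± 1.38; −8.00 without pancreas replicate 3), RRM2 (−7.40 ± 1.18) and CCNB2 (−7.19 ± 0.65). Of 20 residency genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0169, adjusted p = 0.460 with an estimated correlation). Rising members included CXCR6 (3.26 ± 0.80, at 1327 ± 656 and 139 ± 88.1 CPM) and CA10 (8.89 ± 1.40; 10.65 without blood replicate 2). Of 19 TGF-beta response genes, 12 rose and 0 fell (the same count adjusted over the list alone; camera adjusted p = 9.45e-05, adjusted p = 0.105 with an estimated correlation; 7 without blood replicate 1). PMEPA1, a feedback inhibitor of TGF-beta signalling, stood at 6.83 ± 0.61. Of 19 cytotoxicity genes, 7 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0489, adjusted p = 0.785 with an estimated correlation). The granzyme genes GZMK and GZMA stood at −5.00 ± 0.98 and −4.51 ± 0.78, while GZMB did not pass (0.52 ± 0.70, 0.618). PDCD1 was at 249.8 ± 209 CPM in pancreas and 98.6 ± 43.4 in blood and did not pass (1.34 ± 0.86, 0.259), nor did CD101 (0.49 ± 0.55, 0.535) or CCR9 (0.87 ± 1.11, 0.593). IFNG (5.66-fold, 0.0568) passed without pancreas replicate 4 (0.0226 at 2.80) or 5 (0.0496 at 2.69) and with DESeq2 (0.00481 at 2.53); all alternatives gave 0.00481 to 0.161.

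Many NF-kB targets and glycolysis and hypoxia genes rose as well. Not all signalling and metabolic lists did. Of the T cell receptor signalling genes 2 rose and 8 fell, and of the oxidative phosphorylation genes 1 rose and 4 fell. Of the genes of lipid uptake and oxidation 3 rose and 3 fell. Of 23 NF-kB targets, 12 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 0.000143, adjusted p = 0.592 with an estimated correlation). TNFAIP3, which limits NF-kB, stood at 4.05 ± 0.60 and RELB at 3.40 ± 0.75. Of the list 6, 5 and 6 rose without blood replicates 1, 2 and 3. Of 27 glycolysis and hypoxia genes, 13 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 0.000302, adjusted p = 0.592 with an estimated correlation). PFKFB3, which drives glycolytic flux, stood at 3.59 ± 0.73 and VEGFA at 3.69 ± 0.70, and 8 rose without blood replicate 2 or 3. Of the cytokine genes, XCL1 rose by 3.91 and LTB, which encodes lymphotoxin beta, fell by 4.55. The immediate early list was split, with 13 of 31 higher and 6 lower (14 and 7 adjusted over the list alone; camera adjusted p = 0.0532, adjusted p = 0.742 with an estimated correlation; 8 higher without blood replicate 2). ATF3 (4.83 ± 0.66) and NR4A1 (3.79 ± 0.81) rose, and FOS, chosen after its values were seen, fell by 2.31. Markers of other cells moved beside these groups, with 30 of 31 acinar markers higher (camera adjusted p = 1.54e-07, adjusted p = 0.592 with an estimated correlation) and 9 of 11 red cell and platelet markers lower (camera adjusted p = 8.42e-09, adjusted p = 0.133 with an estimated correlation). Duct and epithelial markers were higher (14 of 15, the same adjusted over the list alone; camera adjusted p = 1.97e-05, adjusted p = 0.520 with an estimated correlation). Of 9 NK and gamma-delta T cell markers 5 fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 0.00202, adjusted p = 0.287 with an estimated correlation), beside the falls in circulation and cytotoxicity genes. Of 15 B and plasma cell markers 8 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00270, adjusted p = 0.520 with an estimated correlation), with 5 falling without blood replicate 2. Of 23 macrophage and dendritic cell markers 10 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.00633, adjusted p = 0.742 with an estimated correlation), with 6 falling without blood replicate 1. The number of genes called was 2503 and 2460 without blood replicates 1 and 2.

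Jejunum cells differed from blood at 5832 of 14992 genes, 2832 higher and 3000 lower (5 against 3 libraries), with the same confounding by donors, gate and digestion. They had more RNA of the gut homing receptor gene CCR9 and of residency, activation and chaperone genes, and less of circulation and cell cycle genes. Apart from CXCR6, the libraries of each gene named as rising or falling did not overlap between the groups. CCR9 stood at 334 ± 291 CPM in jejunum and 0.852 ± 0.471 in blood (SD; log2 fold change 8.60 ± 1.47 SE, adjusted p = 0.000430), and CX3CR1 at 4.33 ± 9.24 and 524 ± 116 (log2 fold change −6.90 ± 1.66, adjusted p = 0.00500; −11.36 without jejunum replicate 3, which held nearly all the jejunum counts). Of 20 residency genes, 13 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.000131, adjusted p = 0.166 with an estimated correlation). ITGAE stood at 3.69 ± 0.63, ITGA1 at 4.46 ± 0.84, CD101 at 2.35 ± 0.59 and RGS1 at 7.12 ± 0.88, while ZNF683, which encodes the transcription factor Hobit, fell by 5.15 (6.81 without jejunum replicate 3). ITGA1 stood at 5.96 without blood replicate 3. Of 31 immediate early genes, 22 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 5.51e-11, adjusted p = 0.170 with an estimated correlation). ATF3 stood at 8.29 ± 0.77. All 17 heat shock proteins tested rose (the same count adjusted over the list alone; camera adjusted p = 6.82e-07, adjusted p = 0.520 with an estimated correlation; 13 to 17 with 1 library left out), HSPH1 by 4.56 (3.09 without jejunum replicate 4). HSPA1A and HSPA1B are near-identical, so the value of HSPA1B (5.76 ± 1.36; 4.12 without jejunum replicate 4) cannot be assigned to that gene alone. The number rising among 23 NF-kB targets was 18, with 1 falling (20 and 1 adjusted over the list alone; camera adjusted p = 5.58e-07, adjusted p = 0.497 with an estimated correlation).

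In that comparison 20 of 23 circulation and egress genes fell (the same count adjusted over the list alone; camera adjusted p = 4.55e-10, adjusted p = 0.287 with an estimated correlation). S1PR1 stood at −5.14 ± 0.84. KLF2, in contrast, did not pass (−0.43 ± 0.53, 0.545). Of 27 cell cycle genes, 21 fell (24 adjusted over the list alone; camera adjusted p = 8.29e-09, adjusted p = 0.460 with an estimated correlation). Of 19 TGF-beta response genes 11 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 6.43e-05, adjusted p = 0.105 with an estimated correlation), PMEPA1 by 7.70. AREG, which encodes the growth factor amphiregulin, rose by 6.97, the chemokine receptor gene CXCR4 by 4.92 and the inhibitory receptor gene LAYN by 3.82. CXCR6 (2.44 ± 0.76, 0.0183) overlapped with blood and lost its call without blood replicate 1 (0.0815 at 2.01) or 2 (0.0581 at 2.51), and IFNG (3.20 ± 0.97, 0.0162) lost it without blood replicate 1 (0.0639 at 3.13) or 2 (0.065 at 3.13). For these 2 genes all alternatives gave 0.000752 to 0.0815 and 0.000126 to 0.0650. PDCD1 (−0.02 ± 0.81, 0.990) and GZMB (0.29 ± 0.70, 0.768) did not pass. Acinar markers were higher beside these groups (23 of 31, 29 adjusted over the list alone; camera adjusted p = 0.0196, adjusted p = 0.834 with an estimated correlation). The count was 14 without jejunum replicate 3, and 4, 3 and 4 without blood replicates 1, 2 and 3. Of 23 macrophage and dendritic cell markers 10 fell (camera adjusted p = 0.00647, adjusted p = 0.742 with an estimated correlation). That count was 5 without jejunum replicate 2 or blood replicate 2, 6 without jejunum replicate 5 and 3 without blood replicate 1. Of the NK and gamma-delta T cell markers 3 fell and 0 rose. They summed to 51.0 CPM on average in jejunum (27.9 to 86.8) and 391 in blood (252 to 529). Of the duct and epithelial markers 7 rose, and 1 to 8 with 1 library left out. Red cell and platelet markers fell beside the circulation and cell cycle genes (9 of 11, the same adjusted over the list alone; camera adjusted p = 1.95e-06, adjusted p = 0.205 with an estimated correlation).

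PLN cells held more RNA of activation-induced genes than blood cells, and less of cell cycle genes. The groups also differed in donors, in the CD69 gate and in tissue processing, so site cannot be separated from these. Of 14992 genes, 1942 differed, 1190 higher and 752 lower in PLN (3 against 3 libraries, from other people; limma voom gave 1137 and 1183), and the libraries of each gene named as rising or falling did not overlap between the groups. Of 31 immediate early genes, 26 rose and 0 fell (27 adjusted over the list alone; camera adjusted p = 4.39e-24, adjusted p = 0.105 with an estimated correlation). NR4A1 stood at 1764 ± 1106 CPM in PLN and 2.86 ± 1.18 in blood (SD; log2 fold change 9.27 ± 1.06 SE, adjusted p = 6.1e-05). NR4A2 stood at 7.32 ± 0.77 and ATF3 at 7.97 ± 0.77. Of 23 NF-kB targets, 16 rose (18 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.3e-11, adjusted p = 0.287 with an estimated correlation). TNFAIP3 rose by 5.93 and CD83 by 5.39, and 10 of the list rose without PLN replicate 5 or blood replicate 2 or 3, and 9 without blood replicate 1. Of 20 residency genes, 11 rose (12 adjusted over the list alone; camera adjusted p = 7.18e-07, adjusted p = 0.124 with an estimated correlation; 7 without blood replicate 1). RGS1 rose by 6.25 and CD69, whose protein was sorted on, by 4.28. Of 19 TGF-beta response genes 9 rose (11 adjusted over the list alone; camera adjusted p = 0.000149, adjusted p = 0.105 with an estimated correlation). SKIL, a feedback regulator of SMAD signalling, stood at 4.23 ± 0.49. Of 17 heat shock proteins 11 rose (15 adjusted over the list alone; camera adjusted p = 2.92e-09, adjusted p = 0.456 with an estimated correlation), 7 without PLN replicate 2, and 5, 4 and 6 without blood replicates 1, 2 and 3. BCL6, the transcription factor of follicular T cells, rose by 3.96, GPR183, a receptor that positions cells within lymph nodes, by 2.53 and the chemokine gene CCL20 by 6.18. Of 27 cell cycle genes 16 fell (22 adjusted over the list alone; camera adjusted p = 5.51e-11, adjusted p = 0.369 with an estimated correlation). PLK1 fell by 5.32, and 9 of the list fell without PLN replicate 5 and 6 without blood replicate 1. Red cell and platelet markers fell with them (8 of 11, 10 adjusted over the list alone; camera adjusted p = 3.9e-09, adjusted p = 0.131 with an estimated correlation). That count was 5 without PLN replicate 5 or blood replicate 1 and 4 without blood replicate 2. Acinar markers rose (3 of 31, 20 adjusted over the list alone; camera adjusted p = 0.00189, adjusted p = 0.792 with an estimated correlation), but 0 without PLN replicate 2 or 3 or blood replicate 1, 2 or 3. Of 23 macrophage and dendritic cell markers 2 fell (1 adjusted over the list alone; camera adjusted p = 0.0113, adjusted p = 0.777 with an estimated correlation), 1 without PLN replicate 2, 3 or 5 or blood replicate 1 or 2. Of 9 NK and gamma-delta T cell markers 1 fell (the same adjusted over the list alone; camera adjusted p = 0.00681, adjusted p = 0.369 with an estimated correlation), 0 without PLN replicate 2 or 5.

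Between PLN and blood the receptor and effector genes that did not pass included KLF2 (0.91 ± 0.60, 0.336), CXCR6 (0.91 ± 0.77, 0.468), GZMB (−1.20 ± 0.78, 0.331) and PDCD1 (0.00 ± 0.91, with 98.3 ± 55.0 and 98.6 ± 43.4 CPM). CX3CR1 (−6.30 ± 2.03, 0.0549) and S1PR1 (−2.54 ± 0.92, 0.0810) passed only without PLN replicate 3 (0.0201 at −10.47 and 0.0207 at −3.93) and with DESeq2 (0.00608 and 0.0165), and CD101 (1.61 ± 0.61, 0.0922) only without blood replicate 2 (0.0458 at 2.38) and with DESeq2 (0.0485). For CX3CR1, S1PR1 and CD101 all alternatives gave 0.00608 to 0.152, 0.0165 to 0.229 and 0.0458 to 0.272. ITGAE (2.11 ± 0.62, 0.0314) lost its call without PLN replicate 5 (0.182 at 1.31) or blood replicates 1, 2 or 3 (0.0925, 0.107 and 0.0986, at 2.05 to 2.18), and CCR9 (5.45 ± 1.32, 0.0133) without the same libraries (0.131, 0.0698, 0.0533 and 0.0508). Without PLN replicate 5 the log2 fold change of CCR9 was 2.175, so that library carries most of the value. ITGA1 (2.69 ± 0.80, 0.0346) lost it without PLN replicate 2 (0.0783) or 5 (0.0793), blood replicate 1 (0.122) or 2 (0.144), and without the low-count filter (0.0672), and stood at 4.18 without blood replicate 3. IFNG (3.55 ± 1.03, 0.0314) lost it without PLN replicate 2 (0.0734) or 3 (0.0744), blood replicate 1 (0.117), 2 (0.12) or 3 (0.0859), and without the filter (0.0722). For ITGAE, CCR9, ITGA1 and IFNG all alternatives gave 0.00448 to 0.182, 4.73e-05 to 0.131, 0.00237 to 0.144 and 0.000496 to 0.120. The number of genes called was 1152 and 1244 without PLN replicates 2 and 5, 1001 and 985 without blood replicates 1 and 2, and 2940 with DESeq2.

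**Figure D4:**
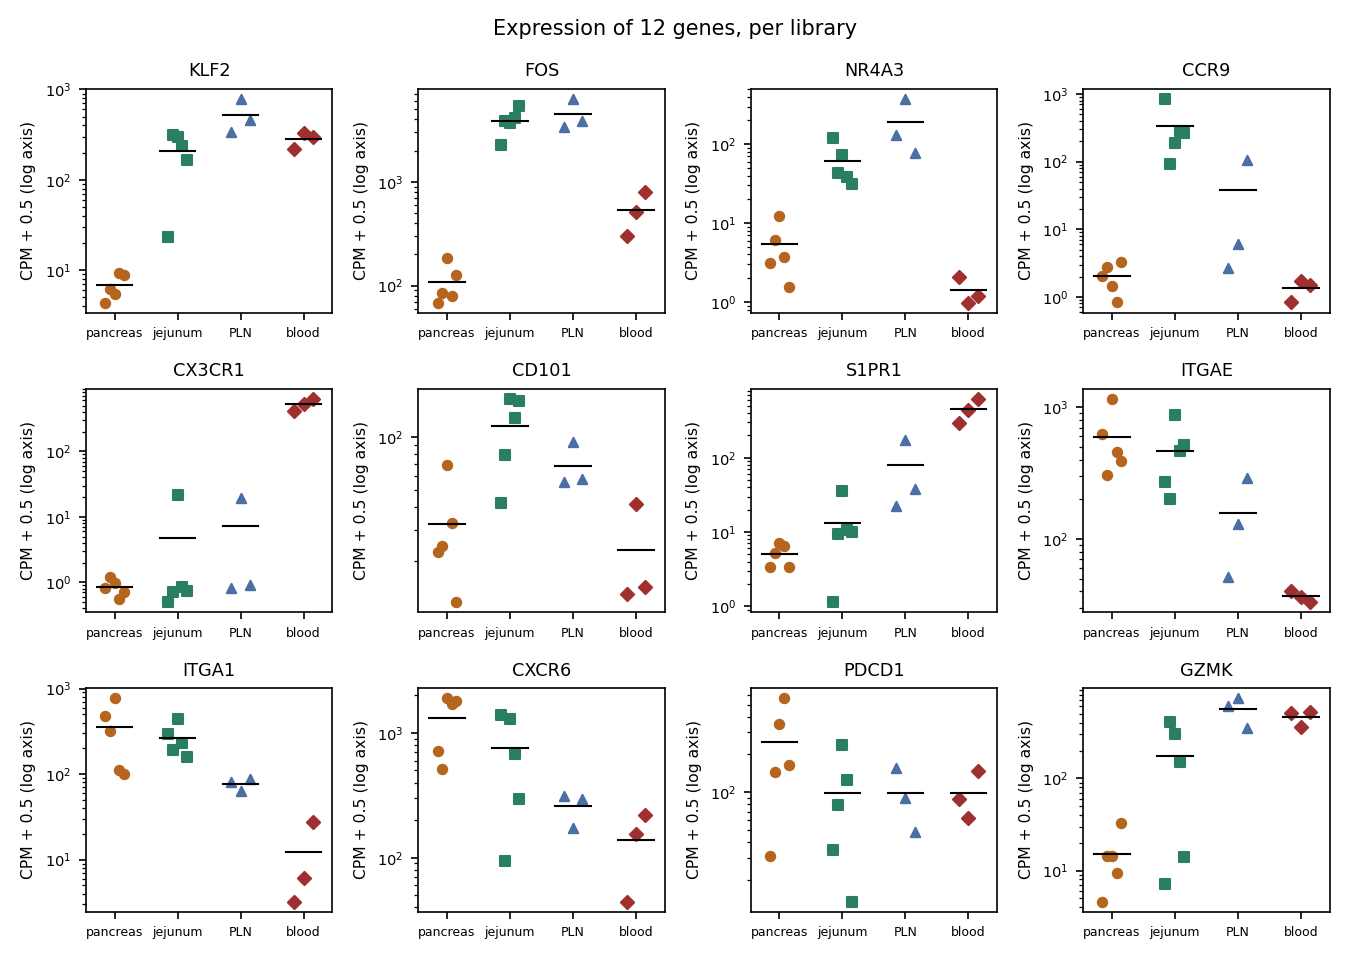
CPM + 0.5 (y axis, log scale) of 12 genes in each library, grouped by site on the x axis; points are libraries and bars are means. KLF2 averages 6.32 CPM in pancreas against 207 in jejunum, while PDCD1 overlaps between all 4 sites.

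All 3 tissues differed from blood in the same direction at 989 genes, 570 higher and 419 lower. The 3 comparisons also share the differences in donors, CD69 gate and tissue processing, so the shared genes cannot be assigned to site. Independent lists of these sizes would share 28.9 and 21.8 genes. The 20 simulations of unchanged tissue groups against shared blood libraries gave 0, as could be foreseen where few genes are called. They do not give the overlap of tissues that do differ from blood. At an unadjusted p under 0.05 the number was 2227, and the simulations gave a mean of 90.9 and at most 113. The 3 blood libraries are shared by these comparisons, can add to the excess and are too few to split. The shared higher genes held 12 immediate early genes, 8 NF-kB targets, 8 TGF-beta response genes, 7 cytokine and chemokine genes, 7 residency genes and 6 glycolysis and hypoxia genes, such as ATF3, TNFAIP3, PMEPA1, RGS1 and PFKFB3. They also held 3 acinar markers (GP2, PRSS1 and REG1A). The shared lower genes held 16 cell cycle genes, 8 red cell and platelet markers and 2 circulation and egress genes (FCGR3A and S1PR4). The count was 610 and 641 without PLN replicates 2 and 5, 443, 413 and 659 without blood replicates 1, 2 and 3, and 1510 with DESeq2.

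Pancreas differed in the same direction from jejunum, PLN and blood at 676 genes, 299 higher and 377 lower. Independent lists would share 28.4 and 34.7 genes. The simulations of unchanged groups gave 0, as could be foreseen where few genes are called. At an unadjusted p under 0.05 the number was 1357, where the simulations gave a mean of 26.9 and at most 38. The 5 pancreas libraries are shared by these comparisons, can add to the excess over either value and are too few to split in 3. The lower genes held 7 circulation and egress genes (CCR7, KLF2, KLF3, KLRG1, PATL2, RASGRP2 and STK38), 6 cell cycle genes, 6 naive and central memory genes, 5 immediate early genes (DUSP1, FOS, JUN, JUNB and MYC), 4 B and plasma cell markers (CD79A, CR2, FCRLA and IGJ) and 3 inhibitory receptor genes (CD160, CD200R1 and TIGIT). The higher genes held 7 duct and epithelial markers (CDH1, CFTR, CLDN4, ELF3, EPCAM, KRT8 and SOX9), 1 acinar marker (PNLIPRP2), 1 islet marker (INS), 2 glycolytic genes (ALDOA and GAPDH) and 2 interferon response genes (IFI44 and IFIT5). Members of these 2 sets are named whether or not the rule for named genes took them, so the names outside it were chosen after their values were seen. The count was 412, 428 and 379 without PLN replicates 2, 3 and 5, 444 without jejunum replicate 4, 386 without pancreas replicate 4, and 1050 with DESeq2.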

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

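The tests of dilution, of the list median without 2 jejunum libraries, of handling, of even spill-over, of mixing, of enzyme level and of the 9 marker genes were chosen after the result was seen. So was the counting of mirrored splits as 1 split. When the other tests were set, the number of genes called without the same libraries was already known.

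Immediate early genes were lower in pancreas than in jejunum, 26 of 31 with a median log2 fold change of −1.82. Dilution by RNA of other cells would lower T cell transcripts alike, but the list's median lay −2.12 from that of T cell receptor signalling genes (0.30). Stress in the 2 jejunum libraries with most acinar or heat shock RNA was to be excluded if at least 0.75 of the 26 calls remained without them. The number called was 19, short of that bound and lowered also by testing fewer libraries, while the median was −1.85. The median thus did not rest on these 2 libraries, but stress across the jejunum libraries cannot be judged this way. Jejunum replicate 1, with 30479 CPM of heat shock transcripts, stayed in, and replicate 3 was left out for its acinar RNA. The jejunum libraries kept held at least 12441 CPM of these transcripts, where the highest pancreas library held 7694. All 5 pancreas libraries lay below the lowest jejunum library in summed level, as either handling of the organ or the tissue itself could give, so a difference between the resident cells stays a hypothesis.

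Of the 299 genes higher in pancreas than in each other group, RNA of acinar cells may account for a part, and how large a part was not settled. Without the 2 pancreas libraries richest in acinar RNA their log2 fold changes against jejunum moved by a median of −0.0930 (quartiles −0.529 and 0.0950), where the acinar markers moved by −2.25, and 156 of them were still called. At 43 of the genes the log2 fold change fell by at least 0.5 of what the acinar markers lost. Most of the 299 genes thus did not move as the acinar markers did. The 9 of these genes that are acinar, duct or islet markers moved by −1.07. The fit without the 2 libraries kept pancreas replicate 4, also rich in acinar RNA (9942 CPM). In it the acinar markers still stood at a median log2 fold change of 2.97, against 5.25 with all libraries. It thus cannot settle whether the 9 markers come from pancreatic epithelium, or how much of the 299 genes acinar RNA explains. With the acinar level as a covariate, which is tied to the tissue, 46 of all genes tested were called higher than in jejunum, against 2311. Summed duct and epithelial markers were highest in pancreas replicates 2, 1 and 4 (2210, 612 and 434 CPM), which also held most acinar RNA. In replicates 5 and 3 they stood at 137 and 80.0 CPM.

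Summed acinar transcripts in jejunum replicate 3 lay apart from the other 4 jejunum libraries (4972 CPM against 53.2 to 175, a gap of 0.737 of the range on the log2 scale). Even spill-over from the pancreas libraries would give like levels in all jejunum libraries. The level was 28.4 times the highest other jejunum library, which restates the observation and is not a separate test. Mixing with the pancreas library of the same number is argued against by a level 2.41 times its own. Jejunal epithelium was to be excluded if PRSS1, CPA1, CPB1, CELA3A and PNLIP held over 50% of the sum; they held 37.9%, but the pancreas libraries themselves gave 31.5% to 53.7%, so that bound was set wrongly. The summed level of these 5 enzymes, 34.3 times that of the highest other jejunum library, argues against epithelium of the jejunum. Acinar cells or free RNA from another source could explain the level and were not tested, and no other biological explanation was tested.

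Between pancreas and jejunum, 28 of 2665 genes called against blood in both went in opposite directions (10 higher and 18 lower in pancreas). All 28 also differed between the 2 tissues by test, which their choice by opposite calls on the same libraries made likely, so it is not separate support. FOS stood at −2.31 in pancreas and 2.84 in jejunum on the log2 scale, DUSP1, a phosphatase gene of the same early response, at −1.96 and 1.37, and CD160 at −1.59 and 3.08. These 3 genes were chosen after their values were seen.

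In 54 sets of 5 libraries, 5 had a library apart, where chance gives 2.7. The number of genes detected was lowest in jejunum replicate 1 (16319 against 16770 to 16923; gap over range 0.747). On the scale of log2 of CPM + 0.5, CX3CR1 was highest in jejunum replicate 3 (4.42 against at most −0.23; 0.859). KLF2 was lowest in jejunum replicate 1 (4.53 against 7.36 to 8.30; 0.752). CX3CR1 was also high in the PLN library of the same donor (replicate 3, 19.19 CPM, against 0.33 and 0.40 in PLN replicates 2 and 5). It was not high in that donor's pancreas library (0.47 CPM).

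Other splits of the libraries tested whether grouping by chance gives as many calls, on the 2 groups of each comparison alone. For pancreas against jejunum the real split gave 4042 genes and the highest of the others 0, with 1 of 100 as large. For pancreas against PLN it was 1720 against 0 (1 of 28) and for jejunum against PLN 1624 against 7 (1 of 28), where 6 of 56 possible splits could not be fitted and 22 were alike or mirrored. Most of these splits part fewer donor pairs than the real one. The splits run that part as many were 12, 4 and 4 for these 3 comparisons, the real one included, with 0 as the highest of the others, and are too few for a share under 0.05. For pancreas against blood it was 4169 against 83 (1 of 56) and for jejunum against blood 6099 against 5 (1 of 56). These shares lie under 0.05, and 1 of 56 is the smallest possible, so chance is made unlikely and is not excluded. In each comparison the other splits mix 2 sites, so a real difference widens their spread and lowers their calls. The splits also leave donors and gate tied to blood. For PLN against blood the real split gave 1960 and the highest other 0 (1 of 10), and 10 splits are too few for a share under 0.05.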

How the results depend on the processing

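The tests without 2 libraries and with the acinar covariate were chosen after the result was seen. Each named gene was counted in each comparison that names it, and 0 of these outcomes changed sign with a call. With RLE 815 kept their side of the threshold and 6 lost the call, with DESeq2 748 kept it, 58 gained and 8 lost, without the filter 769 kept it and 52 lost, and without the donor as a replicate block 346 kept it, 5 gained and 60 lost. With 1 library left out, 5724 outcomes were kept, 46 gained and 767 lost; fewer libraries tested is part of the cause.

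Counts of genes called moved by over 1.5 times as follows, and where libraries were not removed the cause was not tested. A 2-fold threshold gave 2962 for pancreas against jejunum by construction. DESeq2 gave 2159 for jejunum against PLN, 2940 for PLN against blood, 1510 shared tissue genes and 1050 genes distinct to pancreas. Models of the 2 groups alone gave 1720 for pancreas against PLN and 1624 for jejunum against PLN. Without the 2 pancreas libraries richest in acinar RNA, pancreas against jejunum gave 2619 (2375 shared with all libraries). Without the 2 jejunum libraries it gave 2522 (2370 shared), and jejunum against PLN gave 330 (288 shared). The acinar covariate gave 217 (214 shared) for pancreas against jejunum and 409 (396 shared) for pancreas against PLN; it is tied to the tissue, so it removes part of that difference too. Without the replicate block jejunum against PLN gave 234, and the block moved no other count by that much (3589, 2257 and, for genes distinct to pancreas, 554). With an estimated correlation 0 list tests passed, against 81, and 80 passed with RLE and 78 without the genes used to sort.

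Leaving out 1 library gave 3356 to 4862 genes for pancreas against jejunum, 1284 to 3135 for pancreas against PLN, 19 to 1025 for jejunum against PLN, 2460 to 3873 for pancreas against blood, 4169 to 5749 for jejunum against blood, 985 to 2118 for PLN against blood, 413 to 1058 shared and 379 to 686 distinct to pancreas. With donor as a random block in limma voom (correlation 0.255) the counts against blood were 3880, 5758 and 2320. Of 609 outcomes of named genes called, the fold moved by over 1.5 times at 244 with 1 library left out. Depth limits low genes. The simulated recovery of 2-fold changes was 22% at best, but with fewer changed genes than in the data, so recovery in the data is not known. A gene that did not pass is not shown to be unchanged.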

Other observations

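No test in this part was chosen after a result was seen. Interferon response genes went both ways between pancreas and jejunum, with 4 of 31 higher and 5 lower (the same counts adjusted over the list alone; camera adjusted p = 0.802, adjusted p = 0.979 with an estimated correlation). OAS1, an antiviral RNA sensor, stood at 2.62 ± 0.61 and IFI44 at 1.48 ± 0.32, while ISG15, a ubiquitin-like protein, stood at −2.52 ± 0.28 and IRF7, the master regulator of interferon genes, at −2.15 ± 0.33. The higher count became 12 without pancreas replicate 3, and the lower count became 3 without that library, pancreas replicate 4 or jejunum replicates 3 or 4. Of 21 genes of lipid uptake and oxidation, 4 rose and 4 fell (the same counts adjusted over the list alone; camera adjusted p = 0.796, adjusted p = 0.874 with an estimated correlation), and 2 rose without pancreas replicate 4 or jejunum replicates 4 or 5. Against blood the lipid droplet gene PLIN2 (2.43 ± 0.38) was higher in jejunum.

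MAIT-associated genes were compared with blood too, with 8 of 16 lower and 3 higher in pancreas (8 and 3 adjusted over the list alone; camera adjusted p = 0.00955, adjusted p = 0.592 with an estimated correlation; 1 higher without blood replicate 1) and 6 lower and 1 higher in jejunum (6 and 2 adjusted over the list alone; camera adjusted p = 0.160, adjusted p = 0.796 with an estimated correlation). SLC4A10 stood at −6.10 ± 0.60 in pancreas and −5.27 ± 0.58 in jejunum, and IL23R at −6.58 ± 0.95 and −5.00 ± 0.87. The FOXP3 transcription factor gene was higher in pancreas than in jejunum (2.88 ± 0.62, at 18.2 ± 19.0 and 2.89 ± 3.82 CPM), while CD4 was lower (−2.75 ± 0.51). The mast cell markers, at 108 CPM on average in jejunum against 3.62 in pancreas and 6.94 in PLN, ranged from 5.81 to 316 between jejunum libraries (mean 55.8 without replicate 5). Islet markers summed to 7.12 CPM in pancreas, 3.02 in jejunum, 6.21 in PLN (3.53 without replicate 3) and 3.90 in blood.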
